A study of Homo sapiens with 6 samples.

How the data were processed

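Polyadenylated RNA of 6 cultures of the melanoma line A375 was sequenced from stranded mRNA libraries, per the labels' protocols: 3 cultures with 400 µM TTC and 3 with PBS, each for 24 h. The series' design text calls the 3 samples of a group biological replicates. One protocol field names another melanoma line, C918, as the source of the RNA, whereas the title, source and characteristics of every sample name A375, which is used here. Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by the labels' descriptions.

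The authors deposited 1 table of 79643 RefSeq protein-coding transcripts (43003 curated and 36640 predicted models), each with an NCBI gene ID. Every deposited row has a read in at least 1 sample. Per the submitters' processing notes, the tools were fastp, HISAT2, RSEM and DESeq2 and the genome build was GRCh38.p13; versions, parameters and the annotation release are not given in the sources used here. Per the file headers, the table gives for each sample a read count, a TPM and an FPKM. The deposited read counts are expected counts, estimated per transcript with decimals (34.9% are whole numbers) and not normalized. The deposited TPM values sum to 1000000 per sample, within rounding, over these transcripts, and the deposited FPKM values are scaled by the authors to transcript length and library size. The authors' group averages equal the means of the sample columns and were not used. No other column of per-sample values was left out (0 columns). Reads that could fall on several transcripts were shared out by the estimation, so values of paralogs and overlapping genes are uncertain, and transcripts outside the table (non-coding and mitochondrially encoded RNA) were not analysed here.

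For this work the expected counts were summed per gene ID and rounded to whole numbers. Of 17555 gene IDs, 17417 were matched to a symbol in the RefSeq gene table of assembly GRCh38.p14. The 138 others held 0.033% of the reads. That table was used for names and biotypes only, and no coordinates are given because the deposited table holds none. Totals per library were 29644729, 29343363 and 28946965 for PBS replicates 1 to 3 and 28508780, 28424043 and 28435302 for TTC replicates 1 to 3. The 10 most abundant genes held 4.90 to 5.67% of the reads. Replicate pairs differed by 3.90 to 8.89 times the sampling noise (chi-square per degree of freedom), so no library was a copy of another. Counting intervals cover counting error only.

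Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05) with treatment as the only term. Every adjusted p of a gene comes from that fit unless another is named. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-scaled. The biological coefficient of variation was 4.66%. Of 26 gene lists written before the data were examined, the 24 with at least 4 measured members were tested with camera in limma 3.58.1 (log2 CPM with a prior count of 2, preset inter-gene correlation 0.01, 2-sided), and p-values were adjusted over the 24 lists. Camera with an estimated correlation rests on only the few residual degrees of freedom of 6 libraries, and fry tests whether a list's genes move on balance in one direction without comparing them with other genes. Some genes stand in more than 1 list. Of the 562 list entries, 544 were matched to a gene in the table.

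The genes named in the text were fixed by a rule: the 6 with the steepest rise and the 6 with the steepest fall among called genes with a mean of at least 5 CPM and no overlap between groups, the 2 members with the smallest adjusted p of each list that passed camera and 1 of every other list, and 11 genes chosen by name, of which 10 are reported (NEDD8, NAE1, UBA3, UBE2M, CUL1, CDKN1A, MKI67, MITF, DUSP6 and ATF3) and 1 is not reported here. In the Results, genes outside the rule are marked as named after their values were seen. Genes named only under Other observations also fall outside the rule and are not marked there. In addition, each list's median was placed among 10000 random lists matched on mean expression in 20 bins.

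The fits were tested on simulated data made from these libraries' means and dispersions, with 200 of the simulated genes changed. The changed genes were drawn from the more abundant genes only, with as many raised as lowered. Recovery of genes with few counts, and the scaling when most genes change, were therefore not tested. For the TTC against PBS comparison on 13757 genes, the edgeR fit recovered 70% of genes changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 14 unchanged genes. Camera called 3 of 3 simulated raised lists and 0 of 20 unchanged ones. The simulated genes were drawn independently of each other, so false calls from correlated list members were not tested. In the data the estimated correlation reached 0.81, for the cytosolic ribosomal list.

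Alternatives planned before the data were examined were DESeq2's size factors, upper-quartile and library-size scaling, no filter or a stricter one (CPM of at least 1 in 3 samples), DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), protein-coding genes only, the replicate block and leaving out each library. Removing a smooth trend on effective length (from the deposited FPKM and counts) and transcript GC (GENCODE release 29, 98.3% of tested genes) was added after seeing the data.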

Results

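RNA was sequenced from 6 cultures of A375, an established human cutaneous melanoma line. In 3 cultures the medium held 400 µM tetracaine hydrochloride (TTC) for 24 h, and in 3 control cultures it held the same volume of phosphate-buffered saline (PBS). Tetracaine is an ester local anaesthetic that blocks voltage-gated sodium channels. The series title ties the drug to neddylation, the attachment of the ubiquitin-like protein NEDD8 to cullins, and to melanoma proliferation and vemurafenib resistance. The comparison therefore asks which transcripts differed between treated and control cells, and among them those of the neddylation machinery, the cell cycle and the drug-tolerance programmes. Each library held between 28424043 and 29644729 estimated reads, with at least 1 read on 15981 to 16309 genes per library and on 17555 genes over all 6, and 13879 genes entered the test. The first principal component carried 89.1% of the variance and separated the TTC from the PBS libraries.

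Most of the measured transcriptome differed after TTC. Of 13879 genes, 5358 were higher and 5209 lower in TTC at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), which is 76.1% of the genes tested. Changes of 2-fold or more were less even, with 1621 genes higher and 777 lower. The 3 TTC libraries lay wholly above or below the 3 PBS libraries for 77.9% of genes, where chance gives 10%. The median size of the changes that passed was 0.57 on the log2 scale. Scaling by library size alone moved the median log2 change of all tested genes from 0.018 to 0.18 and the share of higher calls from 50.7% to 63.4%, so small changes are relative to the scaling used. Under that scaling 504 genes were lower by 2-fold or more, and on the log2(TPM + 1) scale 307 were, of 1416 that changed by 2-fold or more.

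Among genes with a mean of at least 5 CPM, the TMM-scaled read count per library of 1000000 reads, the steepest rise was that of CA9 (gene ID 768), which encodes the hypoxia-induced surface carbonic anhydrase IX. It went from 0.433 ± 0.063 CPM (SD, n = 3) in PBS to 107 ± 3.39 CPM in TTC, a log2 change of 7.93 ± 0.098 (SE). PRUNE2 rose 45.3-fold, the secreted glycoprotein hormone gene STC1 rose 32.5-fold, the neutral amino acid transporter SLC7A8 rose 27.5-fold, and the neuritin gene NRN1 rose 26.6-fold. INSIG1, an ER protein that retains the sterol sensor SCAP, rose 21.7-fold from 12.2 ± 1.04 to 266 ± 10.9 CPM. The edgeR adjusted p of these 6 genes was at most 2.89e-13. Of all genes named by the rule used here, only ATF3 had overlapping groups. In the others all 3 TTC values lay on one side of all 3 PBS values. The rule itself required this of the steepest genes and picked list members by their small adjusted p. Among all tested genes, 77.9% had groups that did not overlap.

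The steepest falls were those of ANKRD1 and KRTAP2-3. ANKRD1 (gene ID 27063), a cardiac ankyrin-repeat gene widely used as a readout of the transcriptional coactivators YAP and TAZ, had 2355 counts over the PBS libraries and 5 over the TTC libraries, a ratio of 511 (95% exact counting interval 219 to 1574). The keratin-associated gene KRTAP2-3 had 1398 and 4 counts, a ratio of 379 (148 to 1393), and it belongs to a family of near-identical copies between which reads can be split. The ubiquitin ligase MARCHF4 was 81.1-fold lower, the carboxypeptidase CPA4 26.1-fold lower (log2 change -4.71 ± 0.11 SE), and the matricellular protein gene CCN2 26.1-fold lower. The sarcomere protein gene MYPN was 19.1-fold lower. In TTC, MARCHF4 stood at only 0.266 ± 0.0585 CPM and MYPN at 0.499 ± 0.0664 CPM, so their folds rest on few counts.

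Transcripts of cholesterol synthesis rose as a block. All 22 measured genes of the list passed the test upward, 19 of them by 2-fold or more, and the median log2 change was 2.26, a 4.78-fold rise. Besides INSIG1, MSMO1 (a sterol C4-demethylation enzyme) rose 16.3-fold from 11.8 ± 0.466 to 193 ± 7.76 CPM (edgeR adjusted p = 3.61e-18). The list passed the competitive set test camera (adjusted p = 5.64e-12) and also with an estimated correlation (adjusted p = 0.0333), the 1 list of 24 to do so.

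Transcripts induced by the hypoxia-inducible factors (HIF) rose next. Of 24 measured, 22 were higher and 17 by 2-fold or more, with a median log2 change of 1.88. ALDOC, a glycolytic aldolase, rose 20.4-fold from 16.8 ± 0.507 to 342 ± 15.4 CPM, and CA9 is the list's steepest member. The members that did not pass, identified after their values were seen, were ADM at 0.078 ± 0.080 and EGLN3 at -0.13 ± 0.23 (log2 ± SE). Camera's adjusted p for the list was 3.58e-09 (adjusted p = 0.173 with an estimated correlation).

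**Figure D1:**
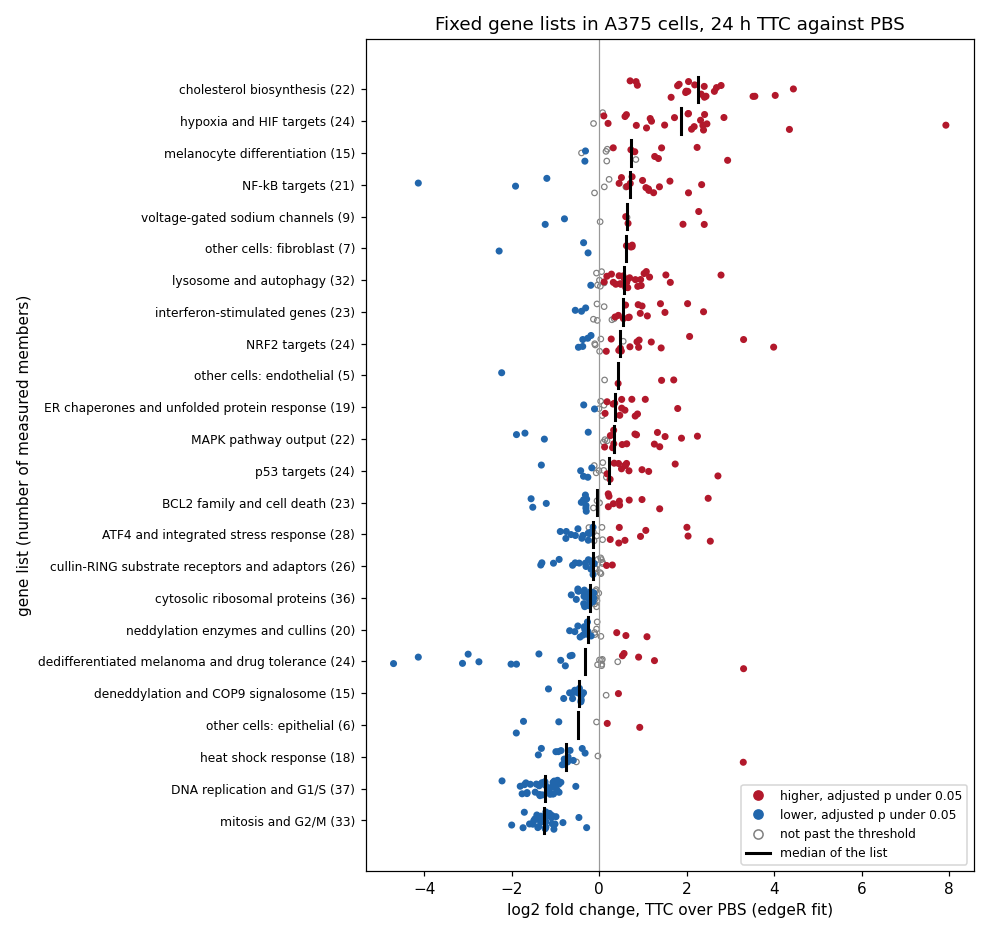
Log2 fold change of TTC over PBS (x axis, edgeR fit, 3 libraries per group) for each measured member of the 24 gene lists with 4 or more members (y axis, sorted by median), with filled points for an adjusted p under 0.05 and a black bar at each list's median. All 22 cholesterol synthesis genes lie above 0, with a median of 2.26, and all 37 DNA replication and 33 mitosis genes lie below 0, with medians of -1.24 and -1.26.

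Proliferation transcripts fell together. All 37 genes of DNA replication and G1/S were lower, 30 of them by 2-fold or more, and all 33 genes of mitosis and G2/M were lower, 29 of them by 2-fold or more. The replicative helicase subunits MCM5 and MCM7 were 4.67-fold and 3.40-fold lower, with MCM5 going from 189 ± 7.54 to 40.4 ± 1.57 CPM. CDC20, the activator of the anaphase-promoting complex, was 4.01-fold lower and the kinesin KIF23 3.35-fold lower. MKI67, the Ki-67 proliferation antigen, fell from 893 ± 65.6 to 329 ± 14.8 CPM. Camera's adjusted p was 2.88e-14 for replication and 1.74e-12 for mitosis (adjusted p = 0.173 for each with an estimated correlation).

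The p53 target list did not pass camera (adjusted p = 0.0899), although CDKN1A, which encodes the cell-cycle inhibitor p21, rose 2.19-fold from 114 ± 5.78 to 249 ± 22.3 CPM. Of its 24 measured genes, 13 were higher and 5 lower (17 and 3 under library-size scaling, which moved the median from 0.21 to 0.37), the latter including the polo-like kinase PLK2 (log2 change -1.32). The list of BCL2 relatives, caspases and their regulators moved in both directions, with 10 genes higher and 10 lower of 23 (camera adjusted p = 0.892), and its median was -0.050 (0.11 under library-size scaling) and its mean 0.029. The anti-apoptotic gene BCL2L1 was 2.95-fold lower, at 50.2 ± 1.11 against 148 ± 11.8 CPM.

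Transcripts of the neddylation pathway changed little in size. Of 20 measured enzymes and cullins, 12 were lower, 3 were higher and 5 did not pass, and the median log2 change was -0.27. Under library-size scaling 8 were lower and 4 higher, with a median of -0.11. NAE1, the regulatory subunit of the NEDD8-activating enzyme, was 1.60-fold lower, from 136 ± 3.61 to 84.9 ± 3.25 CPM (log2 change -0.68 ± 0.046, edgeR adjusted p = 6.33e-10). UBE2M, the main NEDD8-conjugating enzyme, was 1.35-fold lower and the scaffold CUL1 1.26-fold lower. NEDD8 itself (gene ID 4738) was lower by a log2 change of -0.32 ± 0.082, at 59.3 ± 8.14 against 74.0 ± 6.68 CPM (edgeR adjusted p = 0.00196). That call ended under library-size scaling (-0.16, adjusted p = 0.0811), on the log2 TPM scale (-0.12, adjusted p = 0.164) and with a length and GC trend removed (-0.030, adjusted p = 0.661), and held in 14 of 17 settings, the smallest adjusted p being 2.12e-07. The catalytic subunit UBA3 stood at 79.8 CPM in TTC and 85.9 CPM in PBS, a log2 change of -0.11 ± 0.047 that missed the threshold (edgeR adjusted p = 0.0518) and whose sign turned under library-size scaling (0.053). It passed in 5 of 17 settings: with DESeq2's size factors (adjusted p = 0.0386), with no filter (adjusted p = 0.0477), and without PBS replicate 3 (adjusted p = 0.0240), TTC replicate 1 (adjusted p = 0.0475) or TTC replicate 2 (adjusted p = 0.0478), and the highest value was 0.696. The members that rose were CUL7 (1.09 on the log2 scale, 2.13-fold), DCUN1D3 (0.61) and UBE2F (0.40), of which only CUL7 falls under the naming rule, the others being named after their values were seen. The list as a whole did not pass camera (adjusted p = 0.0510), but did without PBS replicate 3 (adjusted p = 0.0382) or TTC replicate 3 (adjusted p = 0.0452). It also passed camera with the replicate block (adjusted p = 0.0467), and camera's settings ranged from 0.0382 to 0.187.

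The COP9 signalosome removes NEDD8 from cullins. Transcripts of the list that holds its subunits, called the COP9 list here, fell more evenly. Of 15 genes for deneddylation and related regulators, 13 were lower and 1, NUB1 (0.44 on the log2 scale, named after its value was seen), was higher. COPS3 was 1.47-fold lower and COPS7B 1.60-fold lower, and the median log2 change was -0.46, or -0.30 under library-size scaling (camera adjusted p = 0.00176, adjusted p = 0.173 with an estimated correlation). Among 26 substrate receptors and adaptors of cullin-RING ligases, 15 were lower and 2 higher, with a median of -0.15 that became 0.011, with 8 lower and 9 higher, under library-size scaling. That median stood at the 28.2nd percentile of random lists matched on expression, whose own median was -0.086. The largest falls named by the rule were those of DTL and CCNF, 2.48-fold and 2.53-fold lower, which are themselves genes of replicating and dividing cells (camera adjusted p = 0.0427 for the list, adjusted p = 0.173 with an estimated correlation). That list did not pass with a stricter filter (adjusted p = 0.0630) or with the length and GC trend removed (adjusted p = 0.0727).

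**Figure D2:**
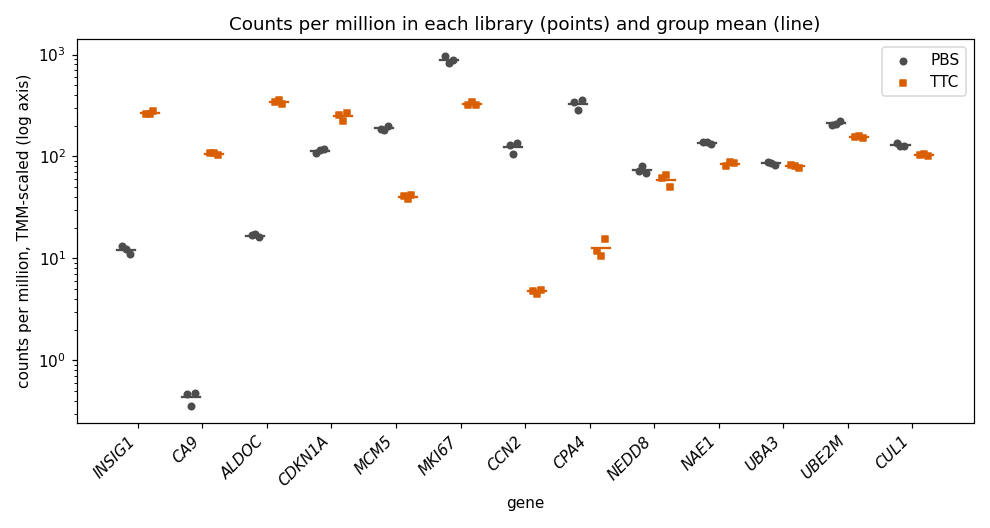
CPM in each library (y axis, log scale, TMM-scaled) for 13 genes named in the text (x axis), with circles for the 3 PBS and squares for the 3 TTC libraries and a line at each group mean. INSIG1 sits at a mean of 266 in TTC against 12.2 in PBS, whereas UBA3 lies at 79.8 against 85.9.

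Genes downstream of cullin-RING substrates, here the NRF2 and NF-κB targets, were more often higher than lower, with some members of each list lower. Of 24 targets of NRF2, the oxidative-stress regulator that KEAP1 and CUL3 mark for degradation, 14 were higher and 5 lower (median 0.47), and camera did not call the list (adjusted p = 0.0510), except without TTC replicate 2 (adjusted p = 0.0229), with a stricter filter (adjusted p = 0.0476) and with the length and GC trend removed (adjusted p = 0.0250), and camera's settings reached 0.518. The median of the NRF2 list stood at the 99.99th percentile of random lists matched on expression. AKR1C2, a hydroxysteroid dehydrogenase whose sequence is close to that of AKR1C1, rose 15.9-fold. The 5 lower members, named after their values were seen, were GCLM (-0.48), SRXN1 (-0.38), TXNRD1 (-0.38), PRDX1 (-0.26) and TXN (-0.19). NQO1, also named after its value was seen, stood at 0.036 ± 0.042. NF-κB targets were higher for 14 of 21 genes, among them TNFAIP3 (4.12-fold), which encodes a feedback inhibitor of the pathway, and the adhesion molecule ICAM1 (2.20-fold). The 3 lower NF-κB targets, named after their values were seen, were IL6 (71 counts in PBS and 4 in TTC, a ratio of 19.2 with an exact interval of 7.20 to 72.6), CCL2 (-1.92) and CXCL1 (-1.20). Camera's adjusted p for the NF-κB list was 0.00928 (adjusted p = 0.252 with an estimated correlation).

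Readouts of MAPK signalling, the pathway that vemurafenib blocks, were higher for 15 of 22 genes, with a median log2 change of 0.33 (camera adjusted p = 0.0130, adjusted p = 0.210 with an estimated correlation). The ERK phosphatase gene DUSP6 went from 121 ± 2.88 to 132 ± 3.65 CPM (1.09-fold, edgeR adjusted p = 0.0178), a call that ended without PBS replicate 3 (adjusted p = 0.0734) or TTC replicate 3 (adjusted p = 0.0994) and held in 15 of 17 settings, down to 2.12e-05. The 2 members with the smallest adjusted p fell instead: the AP-1 subunit FOSL1 was 3.72-fold lower and the receptor tyrosine kinase EPHA2 3.25-fold lower. CCND1 (-1.26) and IER2 (-0.25), named after their values were seen, were the other lower members. Genes linked to dedifferentiated, drug-tolerant melanoma gave 12 lower and 5 higher of 24 (median -0.33, camera adjusted p = 0.0899), with CCN2 the lower member with the smallest p. Under library-size scaling 12 were lower and 10 higher, with a median of -0.17, and camera called the list with the length and GC trend removed (adjusted p = 0.0440), its settings reaching 0.518. Melanocyte differentiation genes gave 8 higher and 2 lower of 15 (median 0.72, camera adjusted p = 0.0756). SOX10, a neural-crest transcription factor, rose 1.65-fold to 729 ± 73.5 CPM, and MITF, the master regulator of the lineage, was 1.24-fold lower at 35.3 ± 1.82 against 43.9 ± 1.35 CPM, a call that ended on the log2 TPM scale (adjusted p = 0.240).

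Lysosome and autophagy genes were higher for 25 of 32 members, with a median log2 change of 0.56 (camera adjusted p = 1.12e-05, adjusted p = 0.173 with an estimated correlation). The autophagosome protein gene WIPI1 rose 6.90-fold and the sialidase gene NEU1 3.09-fold. CD68, a lysosomal glycoprotein used as a macrophage marker and held in the immune list, rose 3.43-fold to 154 ± 9.35 CPM. ER chaperone and unfolded-protein genes were higher for 13 of 19 (median 0.35), among them the co-chaperone DNAJB9 (3.47-fold) and EDEM1 (2.07-fold), which acts in ER-associated degradation (camera adjusted p = 0.0112, adjusted p = 0.465 with an estimated correlation). HSPA5, the principal ER chaperone, named after its value was seen, stood at -0.0064 ± 0.051. The ATF4 and integrated stress response list went both ways, with 9 higher and 13 lower of 28 (camera adjusted p = 0.784). Its median was -0.14 (0.020 under library-size scaling, with 11 higher and 8 lower) and its mean 0.14. ATF3 was at 7.19 ± 1.38 against 8.48 ± 0.611 CPM (edgeR adjusted p = 0.0857, but 0.00262 without TTC replicate 3 and 0.0244 with the replicate block, with settings up to 0.744). The lipoprotein receptor gene VLDLR rose 5.82-fold.

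Cytosolic chaperones fell. Of 18 heat shock genes 15 were lower and 1, the small heat shock protein gene CRYAB (3.29, named after its value was seen), was higher, with a median log2 change of -0.76 (camera adjusted p = 1.07e-04, adjusted p = 0.173 with an estimated correlation). HSPA8, the constitutive HSC70 chaperone, was 2.63-fold lower at 1808 ± 51.9 against 4751 ± 229 CPM, and HSP90AA1 was lower by a log2 change of -1.32. Cytosolic ribosomal protein genes gave 27 lower and 0 higher of 36, with a small median of -0.21 that was -0.053, with 13 lower and 1 higher, under library-size scaling (camera adjusted p = 0.00125, adjusted p = 0.556 with an estimated correlation and 0.130 with the length and GC trend removed, where 20 were lower and 6 higher). RPL35 was 1.56-fold and RPL5 1.44-fold lower. The median of the ribosomal list stood at the 90.9th percentile of random lists matched on expression, so similarly abundant genes fell at least as far. The medians of the 11 lists called by camera other than the ribosomal and substrate receptor lists lay at or above the 98.7th or at or below the 1.19th percentile of such random lists.

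Interferon-stimulated genes were higher for 14 and lower for 3 of 23, with a median of 0.55 (camera adjusted p = 0.0353, adjusted p = 0.173 with an estimated correlation). ISG20, an exonuclease, rose 4.06-fold and IFI35 2.64-fold. Voltage-gated sodium channel genes, the drug's textbook targets, were measured for 9 members, with 5 higher and 2 lower (camera adjusted p = 0.368). Their median log2 change was 0.64 (0.79 under library-size scaling), at the 64.3rd percentile of random lists matched on expression. SCN8A fell from 13.1 ± 0.0383 to 5.55 ± 0.462 CPM, 2.36-fold. Mitochondrially encoded genes were not analysed here.

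Markers of cell types other than melanoma moved in no common direction. The epithelial list gave 3 lower and 2 higher of 6 (camera adjusted p = 0.252), with KRT18 3.32-fold lower at 160 ± 9.02 CPM. The fibroblast list gave 4 higher and 3 lower of 7 (camera adjusted p = 0.784; median 0.62, mean -0.0079), with COL6A3 1.65-fold higher. The endothelial list gave 3 higher and 1 lower of 5 (camera adjusted p = 0.356), with PECAM1 at 1.93 ± 0.324 against 0.589 ± 0.105 CPM. The immune list had 2 measured members, CD68 and LYZ, each higher, and was not tested. Its 8 other markers summed to 0.499 ± 0.122 CPM in TTC and 0.469 ± 0.0957 CPM in PBS, while the pan-leukocyte gene PTPRC, outside the naming rule and chosen after its values were seen, had at most 2 counts in any library. The number of lower or higher members changed in 3 lists when adjusted over the list alone: neddylation 13 lower, p53 targets 14 higher and MAPK readouts 16 higher.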

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

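The removal of the length and GC trend was chosen after seeing the data, the other settings before. Between 9967 (DESeq2) and 10830 genes (no filter) passed over the alternatives, and leaving out 1 library at a time gave 10027 to 10442. DESeq2 called 9956 of the 10567 genes in the same direction. The count of genes lower by 2-fold or more was 777, against 504 with library-size scaling and 307 with limma on log2(TPM + 1), a scale that compresses low genes. On that TPM scale 1416 genes in all changed by 2-fold or more, against 2398, and 65.6% of its calls were higher. Camera with its preset correlation called 13 of 24 lists (13 to 14 without any 1 library), with an estimated correlation 1 list and fry 20. The groups share replicate numbers, but the deviations of same-numbered libraries correlated at -0.035, 0.057 and -0.046, and not every library correlated best with its own number, so the numbers were not taken as pairs. The replicate block gave 10681 genes and 14 lists, the addition being the neddylation list (adjusted p = 0.0467); that list also passed without PBS replicate 3 (adjusted p = 0.0382) and without TTC replicate 3 (adjusted p = 0.0452). Among the named genes the block added ATF3 (adjusted p = 0.0244), and it changed no other call of a named gene or list. UBA3 turned from -0.11 to 0.053 with library-size scaling, 0.089 on the TPM scale and 0.079 with the length and GC trend removed. MITF lost its call on the TPM scale (adjusted p = 0.240). Uncalled lists that turned direction were ATF4 targets with fry (adjusted p = 0.199), and the BCL2 family (adjusted p = 0.935) and sodium channels (adjusted p = 0.816) with the stricter filter. The substrate receptor list did not pass with the stricter filter (adjusted p = 0.0630) or the trend removed (adjusted p = 0.0727), nor the ribosomal list with the trend removed (adjusted p = 0.130). For the calls that were lost or turned, the cause was not tested. Over all alternatives, 970 of the values of named genes and 256 of those of lists kept their direction and side of the threshold, 6 and 15 lost a call, 7 and 14 gained one, and 3 and 3 turned direction. Lists that camera called only under an alternative were the neddylation list, NRF2 targets without TTC replicate 2, with the stricter filter or with the trend removed, and the dedifferentiation list with the trend removed (adjusted p = 0.0440). The alternative for tables without counts (another pseudocount) did not apply. Depth limits genes under about 1 CPM, such as IL6.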

Other observations

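The tests chosen only after the result was seen were the removal of the length and GC trend, which was added after seeing the data, the splits of the libraries, the core NRF2 targets, the immune markers without CD68 and LYZ, and the nearly silent olfactory receptors. Further gene groups, listed after gene changes in other groups had been seen and before their own members were examined, moved with TTC. Transcripts of lipid synthesis beyond sterols rose: of 13 genes listed under fatty acid synthesis and desaturation 11 were higher, with a median log2 change of 0.89. TMEM97 was lower (-0.29), and FADS2 was not called (0.0069). The stearoyl-CoA desaturase gene SCD rose by 2.90 ± 0.046 (log2 ± SE), LPIN1 by 1.89 and the fatty acid synthase gene FASN by 1.35. Ribosome biogenesis genes fell, all 20 of 20, with a median of -1.02, among them the box C/D snoRNP gene NOP56 (-1.52 ± 0.049), NCL (-1.22) and DKC1 (-1.17). The 8 subunits of the cytosolic chaperonin CCT were all lower (median -0.91), and so were 31 of 31 proteasome subunit genes, by less (median -0.47, or -0.31 under library-size scaling). Random lists matched on expression had medians of -0.21 for ribosome biogenesis, -0.33 for CCT and -0.25 for the proteasome, so part of these falls is shared by similarly abundant genes. Camera's adjusted p was 1.69e-04 for the fatty acid list, 3.13e-08 for ribosome biogenesis and for the proteasome, and 7.42e-05 for CCT. With an estimated correlation none of these passed (adjusted p = 0.167 for the fatty acid list and 0.230 for the other 3).

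Targets of YAP and TAZ, coactivators held back by the Hippo pathway, were lower for 18 of 22 genes. ANKRD1, CCN1, CCN2 and AMOTL2 had been seen among the steepest falls, and AXL and GADD45A in other lists. The hypothesis that YAP/TAZ output is lower after TTC was therefore tested on the 16 members not seen before: 12 were lower and 3 higher, with a median of -0.46 (-0.30 under library-size scaling), at the 0.38th percentile of random lists matched on expression. CRIM1 (-1.79), MYOF (-1.78) and F3 (-1.96) fell and NT5E (0.79) rose. The result is consistent with lower YAP/TAZ output as a hypothesis; with an estimated correlation camera's adjusted p was 0.276 for these 16 genes, and cell density, which also sets YAP/TAZ activity, is not recorded in the labels.

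The sterol response raises the question of whether other sterol sensors moved too, and the tests were written down before these lists were examined. If SREBP output rose as a whole, fatty acid genes should rise, and their median stood at the 100th percentile of matched random lists, which is consistent with that. Of the 13 fatty acid genes 11 were higher, whereas TMEM97 was lower (-0.29) and FADS2 was not called (0.0069). If cells also sensed less oxysterol through LXR, its targets should fall. They did not as a set: the 6 LXR targets had a median of 0.40, at the 69.1st percentile. NR1H3 stood at 1.14 ± 0.088, SMPDL3A at 0.85 and LPCAT3 at 0.64, although the cholesterol exporter ABCA1 was at -0.50 ± 0.15. MYLIP (0.0086) and ABCG1 (0.16, at 0.40 CPM in PBS) were not called. The bounds for medians of matched random lists were wide, at -0.42 and 1.00, so 6 genes could hardly show a modest fall. Whether cells sensed less oxysterol through LXR therefore stays open.

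The 22 raised hypoxia genes form the first pattern weighed. A length or GC trend is argued against, since the list's median was 1.91 with the trend removed and 1.88 before. For cells of another type, the test written beforehand left the question open: the highest ratio of summed marker CPM was 3.40, for the immune list, between the bounds of 2 and 4 set for it, and the other 3 lists stayed at or below 1.29. The 3.40 came from CD68 and LYZ, and the 8 other immune markers, examined after this was seen, summed to 0.499 CPM in TTC, which argues against immune cells. A general loss of cullin-RING degradation, which would stabilise HIF and NRF2 alike, may contribute and stays open. The NRF2 targets do not decide it, because their answer depends on the members taken. The 24 listed beforehand had a median of 0.47, with 14 higher and 5 lower. The 8 core targets, chosen after the result was seen, had a median of 0.098, with 4 higher and 3 lower. Lower oxygen in the treated cultures is untested.

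The second pattern is a tilt with abundance. In the lowest eighth of genes by expression (median 0.790 CPM) the median log2 change was 0.50, and in the highest eighth (median 210 CPM) it was -0.28; under library-size scaling these were 0.66 and -0.12. Background from genomic DNA was tested on 77 olfactory receptor genes, whose coding parts have no introns: their summed log2 ratio was 0.16 (95% exact counting interval 0.039 to 0.29), below 0.50, and for the 68 with at most 10 counts on average it was -0.0016 (-0.24 to 0.24). The tilt also kept its size with the length and GC trend removed, at 0.77 between the outer eighths against 0.79. A lower output of abundant growth-related genes in treated cells is the biological explanation left open, and it was not tested.

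The third pattern is the modest fall of the neddylation and COP9 lists, which such a tilt could produce by itself. The neddylation list's median of -0.27 stood at the 9.53rd percentile of random lists of matched expression, whose median was -0.099, so that the tilt may account for it. The COP9 list's median of -0.46 stood at the 1.19th percentile, so few matched lists fell as far. With an estimated correlation camera's adjusted p for the COP9 list was 0.173. The proteasome list (-0.47, 1.23rd percentile) and the CCT list (-0.91, 0.32nd percentile) stood as low, so such a fall was not particular to the COP9 list. The cytosolic ribosomal list, at the 90.9th percentile, did not share it. With the length and GC trend removed the neddylation and COP9 medians were -0.16 and -0.38, against -0.27 and -0.46 before. Such a trend is therefore argued against as the whole of the neddylation or the COP9 fall.

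Other splits of the 6 libraries into 3 and 3 cannot give a share under 0.05, because there are 10 of them. In 1 of the 10, the real split, 10567 genes passed, and the highest of the other splits was 0 (edgeR; 14 to 50 genes at an unadjusted p under 0.05); for changes of 2-fold or more the numbers were again 1 of 10, with 2398 genes against 0. For camera with the preset correlation 3 of 10 splits called at least as many lists as the real 13, the highest of the others being 15. Every mixed split still holds 1 more TTC library on one side and puts TTC and PBS libraries together in each group. The treatment difference then counts as spread within the groups, so the 0 gene calls there say little about chance.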
